A study of Mus musculus with 6 samples.

How the data were processed

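The series holds 6 RNA-seq libraries of mouse lung endothelial cells (MLECs), 3 labelled HEY1-WT KI and 3 labelled HEY1-3KR KI, from mice with an endothelial knockout of Hey1 and a knock-in of HEY1. Per the labels' protocols, cells were cultured in endothelial growth medium with serum, total RNA was extracted, complementary DNA was primed with random hexamers, and the amplified products were denatured and circularised into the final library. How the endothelial cells were purified from lung, the number of mice, and the read length are not given in the sources used here.

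The authors deposited a single table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) for 17463 gene entries with 1 column per library, per the file headers. The submitters' processing notes name FastQC 0.19.7, HISAT2 2.1.0, SAMtools 1.9 and StringTie 1.3.3b and the mouse build mm10. The annotation, the handling of strand and of reads shared between gene copies, and the step from transcripts to genes are not given in the sources used here. FPKM scales each library to its own total, so a rise in a few abundant genes lowers the values of the others, and no scaling between libraries was added. The 17463 entries carried 17450 symbols, 12 symbols stood on more than 1 entry, where the entry of highest mean kept the name, and 292 entries were at 0 in all libraries. Chromosome positions were taken from RefSeq on GRCm38.p6, the assembly that mm10 stands for.

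The labels and the table give no read totals. For 7286 genes with a single transcript, FPKM was multiplied by transcript length. The densest low value within a preset range was taken as the step of 1 fragment, so that range bounded the possible depths. This gave about 19200000, 19600000 and 19700000 fragments for HEY1-WT KI 1 to 3 and 17000000, 16200000 and 19200000 for HEY1-3KR KI 1 to 3. Only 34.4% to 40.4% of the low values lay within 0.1 of a whole multiple of that step, where evenly spread values would give 20%. The step was chosen from the same values, which by itself raises that share. These depths are therefore approximate, whole fragments were not recovered, and no count test was run. At those depths 3 fragments in a transcript of 1 kb correspond to 0.152 to 0.185 FPKM, a floor that covers counting error only. Counting noise for pairs of libraries was estimated from the same steps, for genes with 40 to 2000 fragments in a pair. It was set against the median squared difference between the libraries of a pair. No pair of libraries differed by less than this approximate counting noise, so no pair was merged as 1 library deposited again, which does not show that the libraries came from separate cultures.

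Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested (11432 genes). FPKM was transformed to log2 with a pseudocount of 1, and HEY1-3KR KI was compared with HEY1-WT KI by limma 3.58.1 (R 4.3.3; lmFit and eBayes with a variance trend, two-sided moderated test, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Folds of single genes and FPKM are ratios and means of the deposited values, with the SD over 3 libraries. The cut-offs of 1.5-fold and 2-fold for counts of genes, and the simulated folds, are on the log2(FPKM + 1) scale. The 37 gene lists had 871 entries, of which 20 were matched through a synonym and 13 had no entry in the table. Lists with at least 5 tested members (34) entered limma's camera with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Of these, 16 were called, 14 up and 2 down. When camera instead estimated that correlation from the libraries, 0 lists passed after adjustment and 10 had an unadjusted p below 0.05. The estimate was -0.057 for the arterial list and -0.0052 for cell cycle inhibitors and p53 targets, both below the preset. A higher correlation between members therefore does not account for the loss of those calls. Limma's fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, gave an adjusted p below 0.05 for 30 lists, and its mixed form, which asks for change in either direction, for 31. Shares of summed FPKM were compared by an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3 libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.

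The test, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule names Hey1, Hey2, Heyl and Hes1, then the 12 largest rises and the 12 largest falls among genes that passed with groups that do not overlap (unnamed models, pseudogenes and ribosomal or mitochondrial RNA genes skipped), and up to 4 members of each list by smallest p plus up to 3 of highest mean in lists of other cell types, some of which the text leaves out for length. Members that make up a small count on one side of a list are named as well, and those outside the rule were chosen after their values were seen. A few single genes that the rule or these counts would name are not reported here. The estimate of depth, the comparison with counting noise and the test of NRF2 targets were also chosen after the data were seen.

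The procedure was tested on simulated data for this comparison, with 11432 genes and 50 genes changed at each of 4 sizes. It recovered 66% of genes changed 1.25-fold, 86% of those changed 1.5-fold, 98% at 2-fold and 100% at 3-fold, with 10 false calls among 185. The changed genes were drawn from those with a mean log2(FPKM + 1) above 1, so recovery of lower genes was not assessed. Far fewer genes were changed than the 53.2% called in the real libraries, so these rates need not carry over to them. Over the lists, 0 were called when none was shifted and 1, the cell cycle list, when it alone was raised by 0.3 on the log2 scale. The simulated genes varied independently, which real genes do not: in the 9 other splits of the real libraries into 3 and 3, each with 2 libraries of a genotype against 1, camera with the preset correlation called 6 to 15 lists, so the simulation does not show how often it calls lists falsely in these data. The alternatives were other pseudocounts (0.1 and 0.5), no filter on low values and a stricter filter of 5 FPKM, rescaling to equal sums, median-of-ratios scaling, quantile normalization, the replicate number as a block, array weights, no variance trend, a minimum fold of 2, an estimated correlation between genes, and each library left out in turn.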

Results

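RNA sequencing was carried out on cultures of mouse lung endothelial cells (MLECs), the cells that line lung vessels, isolated from mice that combined an endothelial knockout of Hey1 with a knock-in of HEY1. HEY1 is a basic helix-loop-helix transcriptional repressor that is induced by Notch signalling. One group of mice carried the wild-type protein (HEY1-WT KI) and the other the 3KR form (HEY1-3KR KI). The labels do not spell out 3KR, a kind of name that by convention marks lysine-to-arginine substitutions, which remove lysines that can carry SUMO, a small protein modifier, or other modifications. There were 3 libraries per genotype, 6 in all, and no treatment. The deposited table gave FPKM for 17463 gene entries, with column sums between 258650 and 265967. The densest low values pointed to about 16200000 to 19700000 fragments per library, an approximate estimate. Nothing in the labels says whether the 3 libraries of a genotype came from separate mice or separate cultures, so p-values measure only the spread between these libraries, which may be technical.

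The series, by its title, concerns SUMOylation of HEY1 in endothelial cells, and these libraries compare HEY1-3KR KI with HEY1-WT KI without measuring SUMO attachment itself. In HEY1-3KR KI libraries Dll4, the Notch ligand of arterial and sprouting endothelium, rose from 11.8 ± 0.593 to 33.0 ± 1.46 FPKM, 2.80-fold (SD, n = 3 libraries per genotype). Vwf, the von Willebrand factor of endothelial storage granules, rose 3.56-fold, and Plk1, a kinase that drives mitosis, rose 2.40-fold, from 23.6 ± 0.627 to 56.6 ± 1.02 FPKM. Cdkn2a, a cell cycle inhibitor that accumulates in senescent cells, was 4.97-fold lower, at 14.9 ± 2.23 FPKM in HEY1-WT KI and 3.00 ± 0.465 FPKM in HEY1-3KR KI. Transcripts of macrophages, fibroblasts and lung epithelium also differed between the genotypes and are given beside the endothelial genes. Macrophage and monocyte markers held 2.70% of summed FPKM in HEY1-WT KI and 3.20% in HEY1-3KR KI. Pan-endothelial genes held less, 0.145% and 0.253%. Such shares do not give the share of cells, but values of a whole library need not reflect endothelial cells.

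Hey1, a protein-coding gene on chromosome 3 at 8663359 to 8667038 (GRCm38), read 2.21, 2.16 and 2.25 FPKM in the HEY1-WT KI libraries and 5.71, 5.24 and 4.87 FPKM in the HEY1-3KR KI libraries. Its log2 fold change was 0.97 ± 0.0598 (SE; limma, Benjamini-Hochberg adjusted p = 2.4e-06). Both genotypes carried a knock-in, and the labels do not say whether its transcript is counted under Hey1, so this value does not check the labels. Heyl, a close relative and also a Notch target, on chromosome 4 at 123233556 to 123249870, rose from 1.94 ± 0.198 to 5.33 ± 0.336 FPKM, a log2 fold change of 1.11 ± 0.0674 (limma, Benjamini-Hochberg adjusted p = 2.2e-06). Hes1, a repressor of the same family on chromosome 16 at 30065357 to 30067796, fell from 6.58 ± 0.219 to 5.56 ± 0.268 FPKM, a log2 fold change of -0.21 ± 0.05 (limma, Benjamini-Hochberg adjusted p = 0.00726). Hey2, on chromosome 10 at 30832359 to 30842783, averaged 0.122 ± 0.0658 and 0.212 ± 0.0645 FPKM and was below the filter on low values. Of the 6 tested members of the HES and HEY list, Heyl and Hey1 rose, Hes1 and Bhlhe41, a clock-related repressor, fell, and Bhlhe40 and Hes6 did not pass, while 5 passed when adjusted over the list alone. The median log2 fold change of this list was -0.02 and its mean 0.26, the set test pointed up, and it was not called (camera adjusted p = 0.71).

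Among the 11432 genes tested, 6084 (53.2%) changed at an adjusted p below 0.05 in limma, 3414 higher and 2670 lower in HEY1-3KR KI. The balance of directions depended on the scaling, with 3146 higher and 2911 lower after median-of-ratios scaling and 2911 higher and 3290 lower after quantile normalization. Most of these changes were small on the log2(FPKM + 1) scale, which understates changes of low genes. On that scale 4797 (78.8%) were under 1.5-fold and the median absolute log2 fold change was 0.32. There 370 genes changed at least 2-fold, 247 higher and 123 lower, and low genes above 2-fold by FPKM can be missed. Hey1, at 2.39-fold by FPKM and 0.97 on the log2 scale, is one of those missed. The groups did not overlap in 61.1% of tested genes, against 10% by chance. Libraries of one genotype correlated at 0.994 to 0.996 across genes and libraries of different genotypes at 0.960 to 0.964. Within a genotype, the median squared difference of a pair of libraries was 1.33 to 1.56 times that estimated for counting noise. Between genotypes it was 7.49 to 9.23 times. These are ratios of squared differences, so the differences themselves stand in smaller ratios. The labels give no isolation or culture day, and a batch shared by the libraries of a genotype cannot be told apart from the genotype.

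The largest rises included several genes known from myeloid cells. Rnase2a, an eosinophil-type ribonuclease on chromosome 14 at 51255261 to 51256112, rose from 0.578 ± 0.242 to 26.1 ± 1.92 FPKM, a log2 fold change of 4.11 ± 0.102. Ccl24, the chemokine eotaxin-2, rose from 0.125 ± 0.123 to 15.5 ± 1.65 FPKM, and Cx3cr1, the fractalkine receptor of monocytes and macrophages, rose from 0.818 ± 0.0241 to 18.6 ± 0.287 FPKM. Arg1, the arginase of alternatively activated macrophages, rose from 46.1 ± 0.609 to 263.6 ± 2.67 FPKM. Mmp9, a gelatinase, rose from 0.102 ± 0.0242 to 6.09 ± 0.326 FPKM, and the sizes of the rises of Ccl24 and Mmp9 were uncertain because their HEY1-WT KI values were close to 0. On the log2 scale Lcn2, an iron-siderophore carrier, rose by 2.59, Cd74, the MHC class II invariant chain, by 2.54, and Saa3, an acute-phase apolipoprotein, by 2.53. Saa3 was uneven in HEY1-3KR KI, at 14.7 ± 9.03 FPKM. Cyp26b1, which degrades retinoic acid, rose from 1.57 ± 0.196 to 36.7 ± 1.11 FPKM. Sftpb, surfactant protein B of alveolar epithelium, rose 17.5-fold to 62.0 ± 2.78 FPKM, Slc34a2, the phosphate transporter of the same cells, rose 12.6-fold to 8.41 ± 0.458 FPKM, and Cxcl14, a chemokine, rose 6.21-fold to 30.9 ± 7.51 FPKM.

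The largest falls were led by steroid and detoxification enzymes. Hsd3b6, a steroid dehydrogenase on chromosome 3 at 98805504 to 98814443, fell from 18.2 ± 0.951 to 0.202 ± 0.11 FPKM, a log2 fold change of -4.00 ± 0.0734. The size of its fall was uncertain, because its HEY1-3KR KI mean was near the lowest value that the estimated depths resolve. The glutathione S-transferases Gsta1, Gsta2 and Gsta4 changed by -3.49, -3.31 and -2.52 on the log2 scale, with Gsta4 going from 187 ± 6.87 to 31.8 ± 0.945 FPKM. Adh7, an alcohol and retinol dehydrogenase, changed by -2.35 and Sncg, gamma-synuclein, by -2.88. The prolactin family members Prl2c2 and Prl2c3 changed by -2.77 and -2.05. Itgb7, an integrin subunit of leukocytes, changed by -2.32, Serpinb9b, a serine protease inhibitor, by -2.28, H2-M1, a nonclassical MHC class I gene, by -2.24, and Clca3a1, a gene known from lymphatic endothelium, by -2.17. Gsta1 with Gsta2, Prl2c2 with Prl2c3, Rnase2a with its relatives and the H2 genes have close copies whose reads could have been split between them, so single values within these families are uncertain.

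**Figure D1:**
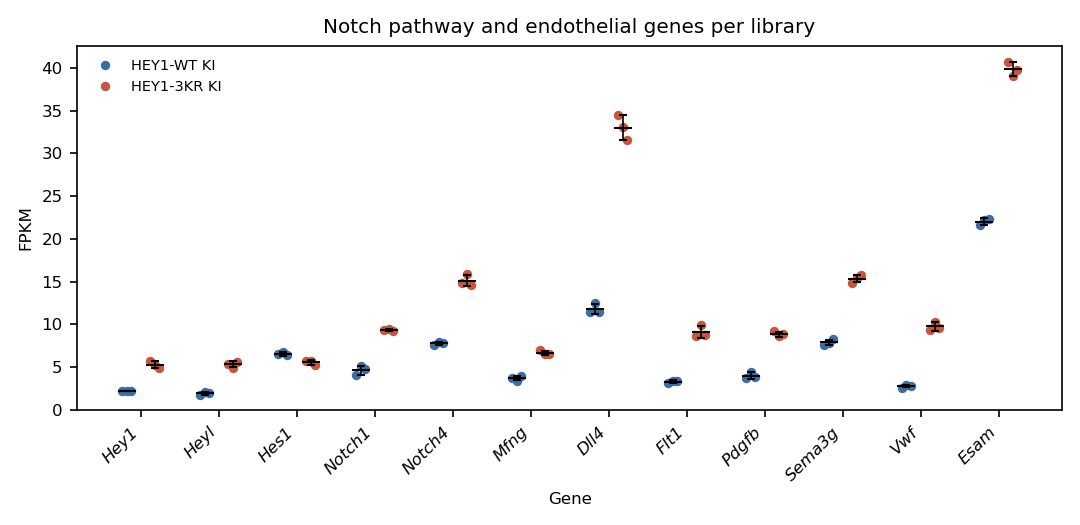
FPKM of 12 Notch pathway and endothelial genes, with 1 point per library, HEY1-WT KI in blue and HEY1-3KR KI in red, and the mean ± SD of 3 libraries in black. Hes1 is the gene that was lower in HEY1-3KR KI, and the other 11 were higher, with Dll4 at 11.8 and 33.0 FPKM.

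Notch pathway genes were mostly higher in HEY1-3KR KI. The rise was not limited to this pathway, since 25 of 27 pan-endothelial genes also rose and none fell (median log2 fold change 0.74). Besides Dll4, the receptors Notch1 and Notch4 rose 2.02-fold and 1.94-fold, to 9.36 ± 0.0734 and 15.1 ± 0.679 FPKM, and Mfng, a glycosyltransferase that modifies Notch receptors, rose 1.79-fold to 6.65 ± 0.277 FPKM. Of 21 tested ligands, receptors and modulators, 14 rose, Dtx3 and Dtx4, members of the Deltex ubiquitin ligase family, fell, and 5 did not pass, with 16 past the threshold when adjusted over the list alone. The median log2 fold change was 0.23, and the list was called by camera, limma's competitive set test (adjusted p = 0.0136 over 34 lists; adjusted p = 0.322 with an estimated correlation). In the SUMO pathway list 13 of 19 members did not pass. Senp1, a SUMO protease, Pias1, a SUMO ligase, Trim28, a corepressor with SUMO ligase activity, and the activating enzyme subunits Uba2 and Sae1 rose, Senp5, another SUMO protease, fell, and 5 passed when adjusted over the list alone (median log2 fold change 0.04, camera adjusted p = 0.71).

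Endothelial genes rose as a group. Plvap, a component of fenestral diaphragms, rose 2.85-fold to 72.5 ± 5.76 FPKM, Cldn5, the claudin of endothelial tight junctions, rose 2.00-fold to 66.5 ± 1.35 FPKM, and Esam, an endothelial adhesion molecule, rose 1.81-fold to 39.8 ± 0.822 FPKM. Of 27 pan-endothelial genes 25 rose, none fell, and Emcn and Mmrn2 did not pass, with 25 past the threshold when adjusted over the list alone (median log2 fold change 0.74, camera adjusted p = 1.4e-10, adjusted p = 0.0837 with an estimated correlation). Pan-endothelial genes made up 0.145% ± 0.00346 of summed FPKM in HEY1-WT KI and 0.253% ± 0.00359 in HEY1-3KR KI (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). In the same libraries the share of macrophage and monocyte markers was 2.70% ± 0.0178 and 3.20% ± 0.0459, that of epithelial markers 0.0704% ± 0.0225 and 0.217% ± 0.0438, and that of fibroblast markers 0.392% ± 0.00576 and 0.547% ± 0.00656 (exact permutation p = 0.1 for each). Smooth muscle and pericyte markers had 0.424% ± 0.003 and 0.436% ± 0.0027 (exact permutation p = 0.1).

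The endothelial lists share members, so their calls are not separate results. Also in another list are 14 of 21 tip cell, 9 of 15 arterial, 9 of 27 pan-endothelial and 5 of 21 lung capillary genes. Of 15 arterial genes 13 rose, Unc5b, a netrin receptor, fell and Cxcl12 did not pass. Among the 13 were Mgp, the matrix Gla protein, 2.04-fold, Cxcr4, the CXCL12 receptor, 2.05-fold, and Sema3g, an arterial semaphorin, 1.94-fold. Hey1 is also among the 13, and its value may include the knock-in transcript. When adjusted over the list alone 14 passed (median log2 fold change 0.60, camera adjusted p = 2.9e-05, adjusted p = 0.0837 with an estimated correlation). Of 21 lung capillary genes 15 rose, including Gpihbp1, the capillary anchor of lipoprotein lipase, 2.92-fold, Kit, the stem cell factor receptor, 2.45-fold, and Fibin 3.40-fold, whereas Kitl, Bmp6 and Sgk1 fell and 3 did not pass. When adjusted over the list alone 18 passed (median 0.36, camera adjusted p = 0.00479, adjusted p = 0.157 with an estimated correlation). Of 21 tip cell genes, which mark the leading cells of sprouts, 13 rose, 6 fell and 2 did not pass, with 20 past the threshold when adjusted over the list alone. Igfbp3 rose 3.20-fold, Trp53i11 2.67-fold and Esm1, endocan, 2.40-fold, while the basement membrane collagens Col4a1 and Col4a2 and the hormone adrenomedullin, Adm, were among those that fell. The tip cell list was called at a median of 0.39 (camera adjusted p = 0.0415, adjusted p = 0.322 with an estimated correlation). That call was lost without HEY1-WT KI replicate 1 (camera adjusted p = 0.0563) and without HEY1-3KR KI replicate 1, 2 or 3 (camera adjusted p = 0.055, 0.0754 and 0.0503), and with the replicate number as a block (camera adjusted p = 0.0608).

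The venous and lymphatic lists went both ways. Of 11 venous genes 6 rose, including Vwf and Ackr3, a scavenging chemokine receptor, 2.42-fold, and 4 fell, including Prss23, a serine protease, from 144.3 to 102.1 FPKM, with 10 past the threshold when adjusted over the list alone (median 0.16, camera adjusted p = 0.382). Of 11 lymphatic genes 7 rose, including the hyaluronan receptor Lyve1, 2.50-fold, and the scavenger receptor Stab1, 3.14-fold, both of which macrophages can also express, and Thy1, Pdpn, Mmrn1 and Nrp2 fell, with 11 past the threshold when adjusted over the list alone (median 0.42, camera adjusted p = 0.312). Of 25 angiogenic receptor tyrosine kinases and ligands 14 rose, 9 fell and Ephb2 and Pdgfa did not pass, with 23 past the threshold when adjusted over the list alone (median 0.29, camera adjusted p = 0.229). Flt1, the VEGF receptor that limits VEGF availability, rose 2.75-fold, Pdgfb, which recruits pericytes, 2.21-fold, and Tie1 1.57-fold, and Axl, a receptor for GAS6, fell from 307.8 ± 15.1 to 184 ± 3.41 FPKM.

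**Figure D2:**
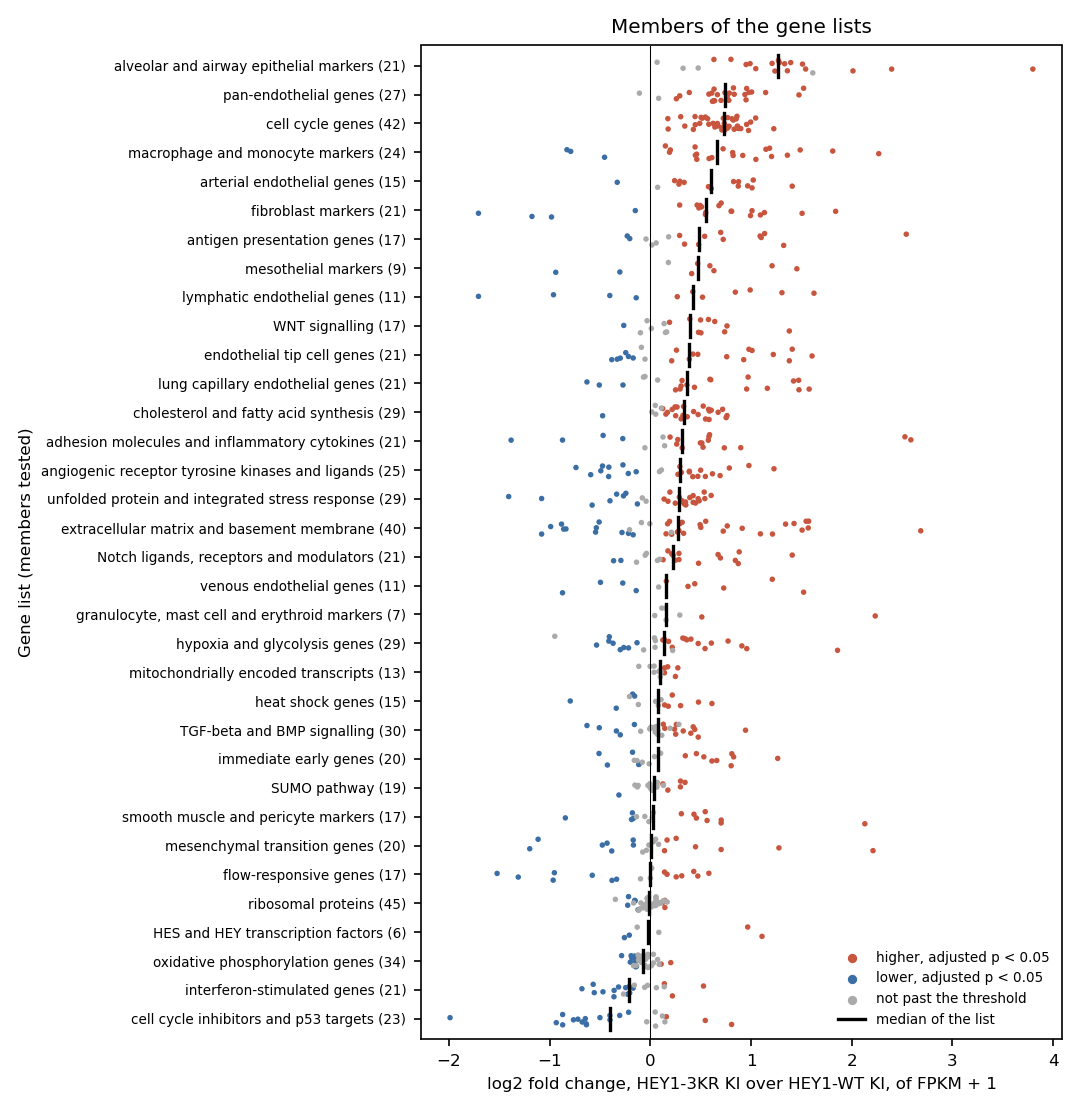
Log2 fold change of FPKM + 1, HEY1-3KR KI over HEY1-WT KI, for each tested member of the 34 gene lists with at least 5 tested members, with points coloured by limma call and a black bar at the median of each list. Epithelial markers had the highest median, 1.27, and cell cycle inhibitors and p53 targets the lowest, -0.40.

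Cell cycle genes rose without exception among those listed. All 42 passed, in limma over all genes and adjusted over the list alone, with a median log2 fold change of 0.73 (camera adjusted p = 7.8e-18, adjusted p = 0.0837 with an estimated correlation). Besides Plk1, the mitotic genes Ccna2, Cdc20 and Aurka rose 2.04-fold, 1.99-fold and 1.86-fold. Of 23 cell cycle inhibitors and p53 targets 15 fell, Cdkn2c, Sesn1 and Trp53 rose, and 5 did not pass, with 18 past the threshold when adjusted over the list alone (median -0.40, camera adjusted p = 6.4e-04, adjusted p = 0.0837 with an estimated correlation). Besides Cdkn2a, the p53 targets Ccng1 and Trp53inp1 were 1.84-fold and 1.96-fold lower, and Eda2r, a TNF receptor family member, went from 10.2 ± 0.337 to 4.85 ± 0.147 FPKM. The shares of macrophage, fibroblast and epithelial markers were also higher in each HEY1-3KR KI library than in any HEY1-WT KI library, and bulk RNA does not show which cells the cell cycle transcripts came from. Of 4 tested histone genes listed as replication-dependent, H2az1 and H1f0, which are not replication-dependent, rose and H2bc4 and H1f2 fell, with 4 past the threshold when adjusted over the list alone and no set test for fewer than 5 members.

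Cholesterol and fatty acid synthesis genes rose in 24 of 29 cases, 1 fell and 4 did not pass, with 26 past the threshold when adjusted over the list alone (median 0.33, camera adjusted p = 3.9e-06, adjusted p = 0.0837 with an estimated correlation). Fdps, farnesyl diphosphate synthase, rose 1.74-fold, Hmgcs1, the HMG-CoA synthase of the mevalonate pathway, 1.69-fold, Sc5d 1.66-fold and Sqle, squalene epoxidase, 1.58-fold. Of 17 WNT genes 10 rose, among them the ligand Wnt2, 3.40-fold, and the receptors Fzd4 and Lrp5, 1.68-fold and 1.46-fold, Ctnnb1, beta-catenin, fell, and 6 did not pass, with 12 past the threshold when adjusted over the list alone (median 0.39, camera adjusted p = 0.00899, adjusted p = 0.157 with an estimated correlation). Of 30 TGF-beta and BMP genes 11 rose, Bmp6, Gdf15, Grem1, Id2 and Smad7 fell and 14 did not pass, with 16 past the threshold when adjusted over the list alone (median 0.07, camera adjusted p = 0.219). Fst, the activin antagonist follistatin, rose 2.65-fold and Bmp6 was 1.47-fold lower. Shares of macrophage, fibroblast and epithelial markers also differed between the genotypes, and bulk RNA does not show which cells the transcripts of these lists came from.

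Of 40 extracellular matrix genes 25 rose, 11 fell and 4 did not pass, with 39 past the threshold when adjusted over the list alone. Thbs1, the antiangiogenic thrombospondin 1, rose 2.94-fold to 439.2 ± 19.1 FPKM, Col3a1 2.89-fold to 118.2 ± 2.63 FPKM and Col6a1 2.77-fold to 57.8 ± 0.133 FPKM. The list shares 8 of its 40 tested members with other lists. It was called at a median of 0.28 (camera adjusted p = 0.0282, adjusted p = 0.541 with an estimated correlation), and the call was lost without HEY1-WT KI replicate 1 or HEY1-3KR KI replicate 2 (camera adjusted p = 0.0563 and 0.0623). The fibroblast markers, which share 7 of their 21 tested members with other lists, rose in 17 cases, and Thy1, Gsn, Serpinf1 and Prrx1 fell, with 21 past the threshold when adjusted over the list alone (median 0.55, camera adjusted p = 0.0021, adjusted p = 0.133 with an estimated correlation). Among them Col1a1 rose from 316.5 ± 4.25 to 676.3 ± 11.9 FPKM and Col14a1 4.24-fold, and Gsn, gelsolin, was 2.27-fold lower. Of 20 mesenchymal transition genes 7 rose, including Tgfbi, 5.43-fold, and Tnc, tenascin C, 2.44-fold, 7 fell, including Cdh2, N-cadherin, 2.38-fold lower, and 6 did not pass, with 14 past the threshold when adjusted over the list alone. The median and mean of this list were 0.01 and 0.07 and the set test pointed down, without a call (camera adjusted p = 0.791). Of 17 smooth muscle and pericyte markers 8 rose, including Kcnj8, a pericyte potassium channel, 6.17-fold, Lmod1, Des, Cnn1 and Myh11 fell and 5 did not pass, with 12 past the threshold when adjusted over the list alone (median 0.03, camera adjusted p = 0.276). Acta2, smooth muscle actin, was at 692.1 ± 5.97 and 707.2 ± 17.5 FPKM and did not pass, but was called lower, at -0.09, after quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.0167).

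Macrophage transcripts were abundant in both genotypes and did not move together. Lyz2, lysozyme, ranked 4 of all genes by mean FPKM, at 3138 ± 51.3 in HEY1-WT KI and 3482 ± 121 in HEY1-3KR KI, and its call was lost after quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.124) and without a filter on low values (limma, Benjamini-Hochberg adjusted p = 0.0992). Itgam, an integrin of monocytes, rose 5.18-fold, Csf1r, the receptor for macrophage colony-stimulating factor, 2.94-fold, and Marco, a scavenger receptor of alveolar macrophages, 2.07-fold to 819.5 ± 29.2 FPKM. C1qa and C1qc, complement subunits made by tissue macrophages, rose 2.58-fold and 2.23-fold. Chil3, the chitinase-like protein of alveolar macrophages, fell from 2093 ± 41.4 to 1528 ± 36.5 FPKM, and Fabp4 and Itgax fell too, so that 21 of 24 members rose and 3 fell, all of them also past the threshold when adjusted over the list alone (median 0.67, camera adjusted p = 1.4e-06, adjusted p = 0.0837 with an estimated correlation). Csf1, the growth factor for macrophages, fell from 367.8 ± 6.52 to 140.5 ± 0.725 FPKM.

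**Figure D3:**
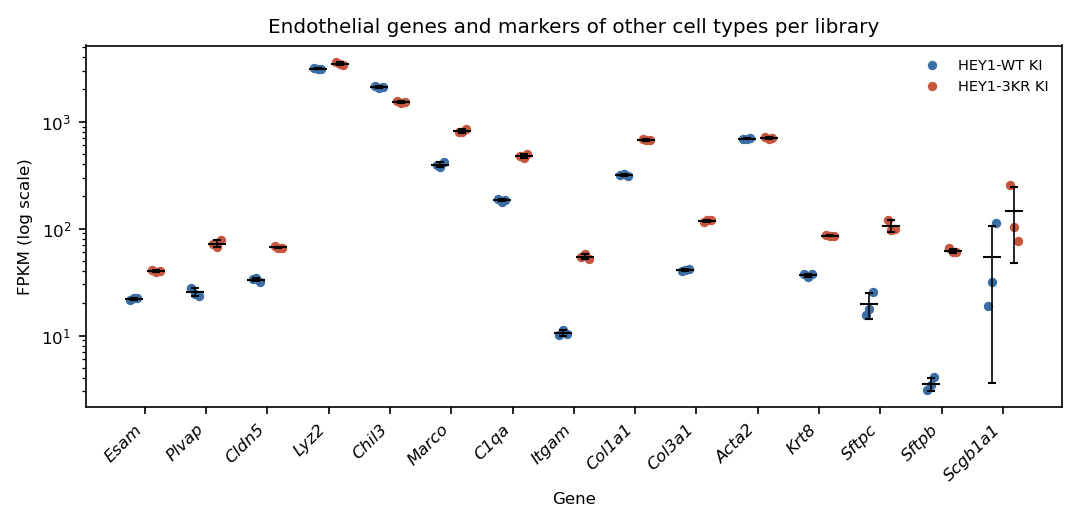
FPKM on a log axis of 3 endothelial genes and 12 markers of other cell types, with 1 point per library, HEY1-WT KI in blue and HEY1-3KR KI in red, and the mean ± SD of 3 libraries in black. Lyz2 and Chil3 have the highest FPKM of these genes in all 6 libraries, Chil3 is lower and Marco higher in HEY1-3KR KI, and Scgb1a1 varies widely between libraries of 1 genotype.

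Epithelial markers rose in 17 of 21 cases and fell in none, while Scgb1a1, Sftpa1, Abca3 and Scgb3a2 did not pass, with 18 past the threshold when adjusted over the list alone (median 1.27, camera adjusted p = 3.4e-09, adjusted p = 0.0837 with an estimated correlation). Sftpc, surfactant protein C of alveolar type II cells, rose 5.39-fold to 106 ± 13.4 FPKM, Muc1, a membrane mucin, 7.50-fold, and the keratins Krt8 and Krt18 2.35-fold and 2.69-fold. Scgb1a1, the secretoglobin of club cells, was at 54.3 ± 50.6 and 146.1 ± 98 FPKM, and passed only without HEY1-WT KI replicate 3 (log2 fold change 2.33; limma, Benjamini-Hochberg adjusted p = 0.00405) or without HEY1-3KR KI replicate 3 (1.98; adjusted p = 0.0376). Of 9 mesothelial markers 6 rose, including complement C3, 3.32-fold, Msln, mesothelin, and Upk1b fell and Wt1 did not pass, with 9 past the threshold when adjusted over the list alone (median 0.47, camera adjusted p = 0.0903). Msln was at 113.6 ± 0.932 and 58.8 ± 0.118 FPKM. Of 7 granulocyte, mast cell and erythroid markers, Pf4, platelet factor 4, rose 4.80-fold to 172.9 ± 3.8 FPKM, Csf3r rose 2.14-fold and 5 did not pass, with 2 past the threshold when adjusted over the list alone (median 0.16, camera adjusted p = 0.252), and the list was called without HEY1-WT KI replicate 3 (median 0.74, camera adjusted p = 0.042). The 1 tested lymphocyte marker, Cd22, did not pass, at 2.56 ± 0.214 and 2.72 ± 0.254 FPKM.

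Antigen presentation genes rose in 11 of 17 cases, H2-T23 and Tap1 fell and 4 did not pass, with 14 past the threshold when adjusted over the list alone (median 0.48, camera adjusted p = 0.0021, adjusted p = 0.322 with an estimated correlation). Besides Cd74, the class II genes H2-Aa, H2-Ab1 and H2-DMa rose 4.79-fold, 3.57-fold and 2.90-fold, from levels of 0.432 to 1.46 FPKM, and with the stricter filter of 5 FPKM the list median was 0.17 and the call was lost (camera adjusted p = 0.193). Of 21 adhesion molecules and inflammatory cytokines 14 rose, including Lcn2 and Saa3, Csf1, Selp, Ptgs2 and Vcam1 fell and 3 did not pass, with 20 past the threshold when adjusted over the list alone (median 0.32, camera adjusted p = 0.0415, adjusted p = 0.322 with an estimated correlation). P-selectin, Selp, was 2.22-fold lower. The call of this list was lost without HEY1-WT KI replicate 1 (camera adjusted p = 0.0606) and without HEY1-3KR KI replicate 1 or 2 (camera adjusted p = 0.096 and 0.0973). Interferon-stimulated genes fell in 12 of 21 cases, 3 rose, including Gbp3 and Trim30a, and 6 did not pass, with 16 past the threshold when adjusted over the list alone (median -0.21, camera adjusted p = 0.0282, adjusted p = 0.157 with an estimated correlation). Irf7, Isg15 and Ifit3 were 1.74-fold, 1.78-fold and 1.79-fold lower, and the call was lost without HEY1-3KR KI replicate 2 (camera adjusted p = 0.0576). The share of macrophage and monocyte markers was 2.70% and 3.20% in the same libraries.

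The remaining lists were not called. Of 29 hypoxia and glycolysis genes 15 rose, 8 fell and 6 did not pass, with 24 past the threshold when adjusted over the list alone (median 0.14, camera adjusted p = 0.143), and Slc16a3, a lactate exporter, rose 4.43-fold. Of 29 unfolded protein and integrated stress response genes 19 rose, 8 fell and Atf3 and Atf4 did not pass, with 27 past the threshold when adjusted over the list alone (median 0.29, camera adjusted p = 0.0957). The chaperones Hspa5 and Hsp90b1 of the endoplasmic reticulum rose 1.46-fold and 1.45-fold, whereas Slc7a11, the cystine transporter, and Ddit3, the stress factor CHOP, were 2.86-fold and 2.20-fold lower. Of 17 flow-responsive genes 7 rose, including Nos3, endothelial nitric oxide synthase, 1.58-fold, 7 fell and 3 did not pass, with 14 past the threshold when adjusted over the list alone. The median of that list was 0.00, its mean was -0.22 and the set test pointed down (camera adjusted p = 0.276). Ranked by smallest p and not by size, its falls began with Nqo1, a quinone reductase, from 202.7 ± 5.96 to 70.0 ± 3.31 FPKM. Next by p were Cyp1b1, a cytochrome P450, 2.86-fold lower, and Ankrd1, a YAP target, 1.95-fold lower. Of 20 immediate early genes 9 rose, including Egr1, 2.78-fold, and Dusp6, a feedback phosphatase of ERK, 1.77-fold, 5 fell and 6 did not pass, with 14 past the threshold when adjusted over the list alone (median 0.07, camera adjusted p = 0.206). Of 15 heat shock genes 6 rose, Cryab, Hspe1, Hsp90aa1 and Hsph1 fell and 5 did not pass, with 13 past the threshold when adjusted over the list alone (median 0.08, camera adjusted p = 0.669).

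Genes of oxidative phosphorylation and translation moved little. Of 34 oxidative phosphorylation genes 9 fell, including Cox6b1 and Atp5b, 1.15-fold and 1.10-fold lower, Cycs and Cyc1 rose and 23 did not pass, with 6 past the threshold when adjusted over the list alone (median -0.08, camera adjusted p = 0.0582). That list was called without HEY1-WT KI replicate 2 (median -0.12, camera adjusted p = 0.00708), without HEY1-3KR KI replicate 3 (camera adjusted p = 0.0143) and with the replicate number as a block (camera adjusted p = 0.0217). Of 45 ribosomal protein genes 37 did not pass, 5 fell, including Rpl22, and 3 rose, including Rpl3 and Rps6, with 2 past the threshold when adjusted over the list alone (median -0.01, camera adjusted p = 0.637). The call of Rps6 was lost without HEY1-WT KI replicate 2, HEY1-3KR KI replicate 1 or HEY1-3KR KI replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0772, 0.0543 and 0.0732). Of 13 mitochondrially encoded transcripts mt-Nd1, mt-Nd2, mt-Nd5, mt-Nd6 and mt-Cytb rose, by 1.19-fold for mt-Nd5, and 8 did not pass, with 2 past the threshold when adjusted over the list alone (median 0.10, camera adjusted p = 0.278), and the list was called without HEY1-3KR KI replicate 3 (median 0.16, camera adjusted p = 0.04997). The calls of mt-Nd6 and mt-Cytb were lost without any 1 of the HEY1-WT KI libraries or HEY1-3KR KI replicate 1 or 2 (for 1 or both genes, limma, Benjamini-Hochberg adjusted p between 0.0566 and 0.105). The share of mitochondrially encoded transcripts in summed FPKM was 5.22% ± 0.159 in HEY1-WT KI and 5.52% ± 0.359 in HEY1-3KR KI (exact permutation p = 0.3). The Y-linked Eif2s3y fell from 11.8 ± 0.652 to 9.95 ± 0.479 FPKM, and Ddx3y, Uty and Kdm5d did not pass, with 1 of these 4 genes past the threshold when adjusted over the list alone.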

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

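The effect of the settings on single gene lists was read after the results were seen. Apart from the minimum fold of 2, which by its construction left 370 genes changed, 247 higher and 123 lower, the count of changed genes stayed between 4268 with the stricter filter, which tested 7415 genes, and 6743 without a filter, which tested 17171, against 6084. Leaving out 1 library gave 5168 to 5467 changed genes, 2841 to 3176 higher and 2231 to 2491 lower, and 12 to 17 gene lists against 16. Genes called higher were 56.1% of calls, 51.9% after median-of-ratios scaling and 46.9% after quantile normalization. The stricter filter left 10 gene lists called: the tip cell, adhesion, antigen presentation, interferon, lung capillary and WNT lists were lost, with fewer genes tested. Array weights also ended the call of the tip cell list; rescaling to equal sums and median-of-ratios scaling added oxidative phosphorylation, quantile normalization added the unfolded protein and mesothelial lists, and no filter added oxidative phosphorylation and mesothelial markers. With the estimated correlation camera called 0 lists (10 at an unadjusted p below 0.05). Of 170 named genes tested, 159 were called, and 154 of these kept their direction and their call under each alternative run for single genes that tested them, which leaves out the minimum fold of 2 and the estimated correlation; Lyz2, mt-Cytb, mt-Nd6 and Rps6 were among those that lost theirs under some. Acta2, which did not pass at 0.03, reversed to -0.0928 and passed after quantile normalization, and the cause was not tested. The values gave no sign that the replicate numbers pair the libraries, although so few libraries cannot exclude it. Deviations of same-numbered libraries correlated at -0.19, 0.25 and -0.27, and 2 of 6 libraries correlated best with their own number. With the replicate number as a block, 6134 genes changed, 3415 higher and 2719 lower, and 16 lists were called, with oxidative phosphorylation in and tip cell genes out. Transcripts under 3 fragments, which is 0.152 to 0.185 FPKM for a transcript of 1 kb, lie below what the estimated depths resolve.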

Other observations

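The tests of NRF2 targets, of evenness within lists and of opposite directions among macrophage markers were chosen after the first results were seen, and those of the splits and of the endothelial median under other scalings were set earlier. After Gsta1, Gsta2, Gsta4, Nqo1, Slc7a11 and similar genes were seen to be lower in HEY1-3KR KI, a list of 35 textbook targets of NRF2, the transcription factor of antioxidant and detoxification genes, was written, 24 of which had not been looked at. Of those 24, 21 were lower, G6pdx was higher, and Osgin1 and Ugdh did not pass (limma, Benjamini-Hochberg adjusted p below 0.05). Prdx1, a peroxiredoxin, went from 653.1 to 293.4 FPKM (log2 fold change -1.15 ± 0.0408, SE), Gstm1, a glutathione S-transferase, from 453.5 to 197.4, Sqstm1, the autophagy receptor p62, from 582.1 to 295.2, Abcc4, an efflux pump, from 41.2 to 16.7, and Txnrd1, thioredoxin reductase, from 199 to 119.9 FPKM (means of 3 libraries). Their median log2 fold change was -0.745 (camera p = 5.5e-12, and p = 0.0129 with an estimated correlation of 0.0958). Nfe2l2, which encodes NRF2, did not pass, at 56.5 ± 1.21 and 55.4 ± 0.336 FPKM (SD, n = 3).

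One hypothesis for this pattern is lower activity of the NRF2 programme in HEY1-3KR KI. It predicts a negative median over targets not looked at before, and that median was -0.745. Another hypothesis is that fewer cells of a type rich in these transcripts may be present, which predicts a negative median as well. The list was written after similar genes were seen to fall in the same libraries, so this median does not favour either hypothesis over the other. These targets moved unevenly, with an SD of their log2 ratios (here and below with a pseudocount of 0.1, for genes with a mean of at least 5 FPKM) 10.6 times the median SE over the 24 targets not looked at before, which argues against an equal fall of all of them. A loss of one cell type stays open, since bulk libraries do not show which cells carry these transcripts or how much of each target other cells supply. A difference in culture stress between the isolations of the genotypes was not tested and is confounded with genotype.

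Endothelial genes were higher in HEY1-3KR KI in 25 of 27 cases, and the scaling between libraries and a larger share of endothelial cells were weighed as explanations. Scaling is argued against: over 3 other scalings the lowest median log2 fold change of the list was 0.684, against 0.74. The members moved unevenly, with log2 ratios with the pseudocount of 0.1 from -0.12 to 1.79 and an SD 7.26 times the median SE over 25 genes. A larger share of endothelial cells, alone or with changed expression within them, could give the pattern and stays open, since bulk libraries do not show how much of each member other cells supply. The difference between the HEY1 forms, which the design names, stays open as well, and the isolation of each genotype may differ in a way these libraries cannot separate from it.

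Macrophage transcripts moved apart, with Itgam, Csf1r and Marco higher and Chil3, Fabp4 and Itgax lower in HEY1-3KR KI. With Lyz2 at a mean of 3310 FPKM and Chil3 at 1810, ranks 4 and 7 in the table, a candidate explanation is that both genotypes' cultures held macrophages; none of the 24 tested markers was in another fixed list, Fabp4 is also known from capillary endothelium, and how cells were sorted is not given. Past limma's threshold 21 members were higher and 3 lower. For markers that macrophages supply more than other cells do, opposite directions argue against a different share of macrophages and nothing else. A marker that other cells supply more could move against the rest. These libraries do not show which cells supply Chil3, Fabp4 and Itgax, so a changed share alone stays open. The counts are the values that drew attention to the pattern, not a separate test of it. A different mix or state of macrophages between the genotypes, which might follow from the genotype or from the isolation, stays open.

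The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The genotype split was the 1 of 10 that gave the most, with 6084 genes changed, 3414 higher and 2670 lower, where the highest of the other splits gave 0 by limma in each count (48 to 240 genes at an unadjusted p below 0.05). Every other split mixes the genotypes on both sides, so the difference between them widens the spread within each side. Low gene counts there follow from the design, and the contrast cannot decide about chance. For gene lists the genotype split was again 1 of 10, with 16 lists called against 15 for the highest and 6 for the lowest of the others, in splits that still keep 2 libraries of a genotype together on each side.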
